A study of Canis lupus familiaris with 8 samples.

How the data were processed

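Total RNA from canine mammary tumour cells, grown in medium with 10% fetal bovine serum at 37 °C and 5% CO2, was extracted with a column kit, treated with DNase and used at an RNA integrity number of 7 or more, per the labels' protocols. From each sample 100 ng was labelled with Cy3 and hybridised to a 1-colour Agilent miRNA array. The 8 samples fall into 4 groups of 2: the doxorubicin-sensitive line Stylo, the resistant line Star derived from it, and CSC sorted from each as CD44-positive, CD24-negative or low, aldehyde dehydrogenase-positive cells.

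The scanner files hold spot intensities that Agilent Feature Extraction 11.5.1.1 measured and background-subtracted, per the file headers and the submitters' processing notes, with flags for spots well above background, saturated or outlying, and a total per miRNA that the software sets to 0.1 where it detects none. The deposited value table holds log2 values of those totals, whose shift and centring the labels do not state. Setting it against the scanner files showed that differences between columns equal differences of log2 totals after 1 shift per array (tolerance 0.01), with each miRNA centred on its median over the 8 arrays. The direction is therefore known, and the labels do not give the reason for the shifts.

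The 475 entries of the table all followed the scanner totals in 6 columns. For Stylo CSC replicate 1 and Stylo parent replicate 2, 420 and 417 did, so those 2 columns hold other values than their scanner files. Most of their entries were undetected in both sources and matched for that reason. The scanner files detected 38 and 48 miRNAs on these 2 arrays, and the columns held 30 and 25. The column medians were −0.941, −0.635, 0.0127, −0.116, 6.15, −0.0127, 0.293 and 6.15 in the order Star CSC 1 and 2, Star parent 1 and 2, Stylo CSC 1 and 2, and Stylo parent 1 and 2. The shift of each array followed the log2 of its 90th percentile of totals, with sums of 2.75 to 2.83, as a scaling to that percentile would give.

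On each array, spots of 1 probe were averaged on the linear scale after leaving out control spots and outlier flags (3.84% to 9.15% of spots). The 2 to 4 probes of a miRNA (998 probes for 454 miRNAs) were summed. Each array was divided by the 75th percentile of its signal over the 22 probes well above background on all arrays, a common floor was set at a scaled signal of 0.0822 (log2 −3.61, the median over arrays of the lowest signal among miRNAs well above background), and log2 was taken. A probe counted as well above background where over 50% of its spots did, and a miRNA where any of its probes did. The 46 miRNAs well above background on every array of at least 1 group were tested.

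Groups were compared with limma 3.58.1 in R 4.3.3, in a single fit of 4 group means with 7 arrays and 3 residual degrees of freedom, two-sided. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within a comparison. The contrasts were Star parent against Stylo parent, Stylo CSC and Star CSC each against their parent, Star CSC against Stylo CSC, and the difference of the 2 CSC changes. A miRNA not well above background on any array of a group has only a bound there. It is written as at least N-fold, from the brighter group's mean against the dimmer group's mean of the higher of its own signal and the lowest signal of miRNAs well above background. No bound is given where it lies under 1, and a log2 change beside a bound is a distance to the floor or to a dim signal. Arrays at the common floor show no spread, so errors and p-values of such miRNAs are too small, most of all on slide 1. Errors are limma's standard errors. The number of arrays limits the precision.

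Families (let-7, miR-200, miR-183, miR-17-92, miR-34, miR-15, miR-23/27/24, miR-29, miR-30, miR-221, miR-125, miR-181, miR-26, miR-130, miR-148, miR-103, miR-302, miR-500 and DLK1-DIO3), functions (oncogenic, tumour-suppressor, breast cancer stem cells, drug efflux or doxorubicin resistance) and other sources (haematopoietic, muscle, neural, endothelial, liver, mesenchymal, epithelial and serum-abundant) were listed before the data were examined, as were the groups, the tests and most alternatives. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, and again with an estimated correlation. No list call held with the estimated correlation (0 calls in the 3 sets). The lists overlap: let-7a, let-7b, let-7c and miR-34a stand in the stem cell list and in another, and miR-155, miR-92a and miR-223 in several. Named miRNAs were, per comparison, up to 10 rises and 10 falls past the threshold whose arrays do not overlap, up to 3 members per list past the threshold, and, where fewer than 5 passed, the 3 highest and 3 lowest values among the 10 smallest p-values. MiR-21, miR-200c, miR-34a, let-7a, miR-210 and miR-221 were named in every comparison, and miR-200c was not well above background on any array. MiRNAs named because they passed in both further sets were chosen after their values were seen.

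The scanner files of Stylo parent 1 and 2 held identical values and entered as 1 sample. Slide and scan split the arrays in the same way (2 slides, 2 scans), and slide 2 held only the array of Stylo CSC replicate 1, so a slide block keeps the 7-array scaling and leaves that array no weight. The slide 1 set was scaled anew over 39 reference probes (floor log2 −2.99, 50 miRNAs tested, 2 residual degrees of freedom). For the recovered totals, differences of the table's columns to that of Star parent replicate 1 were added to that array's scanner total, each column's most frequent offset was removed, and scaling over 22 miRNAs detected on all 8 arrays, floor (log2 −4.89) and fit followed as above (56 miRNAs tested, 4 residual degrees of freedom). In this set a miRNA counts as above background where its total lies above the undetected value. Both sets were chosen after the data were examined. A Stylo group with 1 array is assumed to vary like the other groups.

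The limma call was tested on simulated log2 values with known changes (10 miRNAs per run, 20 runs). Probe sums, scaling, the floor and the difference of the 2 CSC changes were not simulated. Every group was given the same spread for a miRNA, which with 6 arrays came from the Star arrays alone. The rates therefore do not cover miRNAs at the floor or the spread of the Stylo groups. With 7 arrays and 46 miRNAs, 24% (Star against Stylo parent), 31.5% (Stylo CSC against parent), 41.5% (Star CSC against parent) and 45% (Star CSC against Stylo CSC) of 2-fold changes were recovered, and 72.5%, 77.5%, 81% and 84.5% of 4-fold changes. With 6 arrays and 50 miRNAs, 94%, 91%, 99% and 92% of 2-fold changes and 99.5%, 99%, 100% and 100% of 4-fold changes were recovered. False calls per run were 0.15 to 0.65 with 7 arrays and 0.3 to 0.95 with 6.

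Alternatives were scaling over all probes, quantile normalization and no scaling; the deposited totals, the brightest probe or the mean of log2 probe values in place of the sum; no filter or a stricter filter on dim miRNAs; a lower floor; a trend in eBayes; only the groups compared; an unadjusted p with a 2-fold change; the replicate number or slide as a block; the deposited value table as it stands; both identical files entered separately; normexp background correction (offset 50) on the median spot signal; and leaving out each array. MiRNA names are those of the array design, and 445 of 454 (55 of the 56 tested in the recovered totals) matched a gene of the reference table of assembly UU_Cfam_GSD_1.0, which was used only for names and neighbours. MIR23B and MIR27B, and MIR23A and MIR27A, are neighbours there with 0 genes between them. No coordinates are given, since the array was designed on another assembly. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and files were read with jsonlite 2.0.0 and with version 1.17.8 of data.table.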

Results

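MicroRNA levels were measured in 2 related canine mammary tumour cell lines and in stem-like cells sorted from each. CMT-Stylo (Stylo) is a mammary adenocarcinoma line. CMT-Star (Star) was derived from it by raising doxorubicin, a DNA-intercalating chemotherapy drug, until the cells grew in 100 nM. Cells carrying CD44 and aldehyde dehydrogenase activity, with little or no CD24, were sorted by flow cytometry from each line and are called CSC here, as in the labels. The 4 groups (Stylo parent, Stylo CSC, Star parent and Star CSC) had 2 samples each, hybridised to 1-colour Agilent arrays with probes for 454 canine miRNAs.

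Between 4.19% and 8.78% of the 18160 spots of an array were well above background, and 54 of the 454 miRNAs were so on at least 1 array. The Star CSC arrays measured 49 and 43 miRNAs well above background, the Star parent arrays 35 and 40, the Stylo CSC arrays 24 and 40, and the Stylo parent array 33. No spot was saturated (0 on every array). The scanner values of Stylo parent replicates 1 and 2 were identical, so they differed by less than any noise and were counted as 1 sample, which leaves n = 1 for Stylo parent and 7 arrays in the fit. Let-7b, let-7a and let-7e had scaled log2 signals of 2.98, 2.29 and 0.96 in Star CSC. The miR-200 family, which maintains the epithelial state, was not well above background on any array (0 of 5 members), nor were the lists of muscle (0 of 8), mesenchymal (0 of 5), epithelial (0 of 8), endothelial (0 of 1) and liver miRNAs (0 of 1).

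The array of Stylo CSC replicate 1 lay on slide 2 and all others on slide 1. Over the 17 miRNAs well above background on every array it correlated with the other arrays at r = 0.544 to 0.614, against 0.931 to 0.999 for all other pairs. Over all 46 tested miRNAs these ranges were 0.762 to 0.807 and 0.935 to 0.998. Each comparison is therefore given first over all 7 arrays and then in 2 further sets chosen after the data were examined. The slide 1 set holds the 6 arrays of slide 1, with 1 array each for Stylo CSC and Stylo parent. The recovered totals are the deposited value table turned back into log2 totals, which holds 8 arrays with other values for Stylo CSC replicate 1 (r = 0.961 to 0.979 with the other columns over 22 miRNAs detected in every column, and 0.864 to 0.94 over all 56 tested) and for Stylo parent replicate 2. The 2 further sets share 6 arrays, so a change that passed in both rests largely on the same arrays. Leaving out Stylo CSC replicate 2 in place of replicate 1 raised the counts as well, to between 31 and 36 miRNAs per comparison, so the higher counts do not single out replicate 1. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

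Star parent was compared with Stylo parent to see which miRNAs accompany doxorubicin resistance. MiR-155, an oncogenic miRNA abundant in activated immune cells, was lower in Star parent. It was well above background on the Stylo parent array and on 0 of 2 Star parent arrays, at least 2.08-fold lower in Star (log2 change −1.06 ± 0.12 SE, n = 2 and 1; limma, adjusted p = 0.035). On 5 of the 6 arrays of the other groups it lay at the floor, so this error holds little measured spread. It was the 1 miRNA of 46 tested to pass (0 higher, 1 lower), and 6 had an unadjusted p below 0.05. In the recovered totals miR-155 was detected in both lines and fell by 1.72 ± 0.05 (n = 2 and 2, adjusted p = 3.81e-05).

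In the slide 1 set 20 of 50 miRNAs passed (10 higher, 10 lower) and in the recovered totals 18 of 56 (10 higher, 8 lower), and 14 passed in both with the same sign. MiR-16, miR-30d, miR-223 and miR-8892, all lower in Star, passed on slide 1 but not in the recovered totals, where their sign was opposite. In these totals all 4 lay at the floor on Stylo parent replicate 2. On replicate 1 each lay above both Star parent columns, so the opposite sign rests on 1 column at the floor. The 8 higher in Star included miR-29a, which targets collagen transcripts, with log2 changes of 1.03 ± 0.07 on slide 1 and 1.13 ± 0.07 in the recovered totals. MiR-23b rose by 0.84 and 0.78, its genomic neighbour miR-27b by 0.49 and 0.83, miR-23a by 0.51 and 0.53, and miR-22 by 0.71 and 0.71. MiR-191, miR-93 and miR-210, which hypoxia induces, were not well above background in Stylo parent on slide 1, which makes miR-191 at least 1.54-fold and miR-210 at least 1.14-fold higher in Star, with no bound for miR-93. MiR-93 and miR-210 were undetected in Stylo parent in the recovered totals, at least 1.65-fold and 1.68-fold higher in Star, and miR-191 rose by 1.61 with 1 of 2 Stylo parent arrays at the floor. Those lower in Star included miR-92a of the miR-17-92 clusters (at least 3.23-fold on slide 1, and −2.04 in the recovered totals) and miR-155 (at least 1.75-fold, and −1.72). The others were miR-15b (2.01-fold lower on slide 1, and −1.06 in the recovered totals), let-7b (−0.61 and −0.65), let-7e (−0.48 and −0.60) and miR-494 (−0.20 and −0.25, but 0.09 in the recovered totals without scaling). The 3 measured members of the miR-23/27/24 clusters all rose in both further sets. As a list they passed camera in the recovered totals (adjusted p = 0.0345, but adjusted p = 0.477 with an estimated correlation) and not on slide 1 (adjusted p = 0.0618). The list did not pass over all 7 arrays (adjusted p = 0.345), and its median of 0.26 turned to −0.21 with scaling over all probes. Of the 6 measured let-7 miRNAs, whose targets include RAS and HMGA2, 4 fell in the recovered totals (camera adjusted p = 0.0306, adjusted p = 0.293 with an estimated correlation, 4 adjusted over the list alone), with a list median of −0.31 that turned to 0.02 without scaling.

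Over all 7 arrays the values of other miRNAs chosen by the rule set beforehand did not pass in Star against Stylo parent (adjusted p from 0.149 to 1). Above 0 were miR-103 (log2 change 0.31) and miR-34a, a p53 target (0.09). MiR-191, miR-210 and miR-874 lay at the floor in Stylo parent, so that 0.89, 0.45 and 1.4-fold are their distances to it, with a bound of at least 1.29-fold for miR-191 and none for the other 2. Below 0 were miR-221 (−0.01), let-7a (−0.42), let-7c (−0.52), miR-21 (−0.66) and miR-15b (2.39-fold). With the slide as a block 32 miRNAs passed (10 higher, 22 lower), miR-155 among them at −1.06 (adjusted p = 0.000372). The miR-155 call ended in 15 of 23 alternatives (adjusted p up to 0.823), among them without scaling and without any 1 of the 4 Star arrays. The recovered totals gave 6 miRNAs without Star parent replicate 1.

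Star CSC were compared with the Star parent to see what distinguishes the sorted cells of the resistant line. MiR-31, a suppressor of metastasis in breast cancer models, was well above background on 2 of 2 Star CSC arrays and on 0 of 2 Star parent arrays, at least 1.96-fold higher in CSC (log2 change 0.97 ± 0.10, n = 2 and 2; limma, adjusted p = 0.0318). It was the 1 miRNA of 46 to pass (1 higher, 0 lower), with 10 at an unadjusted p below 0.05. It was at least 1.86-fold higher on slide 1 (1.05 ± 0.10, adjusted p = 0.00759) and at least 2.85-fold higher in the recovered totals (1.51 ± 0.09, adjusted p = 0.000778). On every array outside Star CSC miR-31 lay at the floor, over all 7 arrays and in the recovered totals. Its errors there hold measured spread from the 2 Star CSC arrays alone, and it was tested only through them. With normexp on the median signal its value turned to −0.09.

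In Star CSC 17 miRNAs passed in both further sets, 9 higher and 8 lower, from 26 of 50 on slide 1 (14 higher, 12 lower) and 20 of 56 in the recovered totals (11 higher, 9 lower). Without scaling the balance turned, to 20 (18 higher, 2 lower) in the recovered totals and 11 (11 higher, 0 lower) over all 7 arrays. Let-7 members, which promote differentiation, rose together: let-7c by 0.57 and 0.67, let-7f by 0.45 and 0.56, let-7a by 0.45 and 0.55, let-7e by 0.42 and 0.52, and let-7b by 0.27 and 0.37. MiR-15b, which targets BCL2, rose by 0.65 and 0.93, miR-34a by 0.40 and 0.50 and miR-21, an oncogenic miRNA, by 0.39 and 0.49. MiR-22 fell by 1.71 ± 0.11 and 1.54 ± 0.13, the largest fall in both sets, followed by miR-29a (−0.91 and −0.99), miR-125b (−0.91 and −0.81), miR-193a (−0.86 and −0.70) and miR-27b (−0.65 and −0.55). MiR-494 (−0.45 and −0.35), miR-23b (−0.42 and −0.32) and miR-331 (−0.32 and −0.22) fell less, and in the recovered totals these 3 turned to 0.17, 0.20 and 0.30 without scaling.

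The let-7 family passed camera as a list in Star CSC over all 7 arrays (median log2 change 0.52, adjusted p = 0.0218, but adjusted p = 0.381 with an estimated correlation). None of its 6 members passed there over all miRNAs (0 of 6 by limma, 3 at an unadjusted p below 0.05) and 3 passed adjusted over the list alone. On slide 1, 6 of 6 rose (6 adjusted over the list alone; adjusted p = 0.00522, and adjusted p = 0.897 with an estimated correlation), and in the recovered totals 5 of 6 (5 adjusted over the list alone; adjusted p = 0.00706, and adjusted p = 0.182 with an estimated correlation). With the slide as a block the list had adjusted p = 0.00662 (adjusted p = 0.536 with an estimated correlation). The list median lay above the median of all tested miRNAs by 0.52 to 0.64 across the 4 scalings of the scanner values, but the call ended under each of the 3 others (camera adjusted p = 0.438 with scaling over all probes, 0.259 with quantile normalization and 0.732 without scaling). Let-7 sequences differ by few bases and the array may not separate them fully, so the members are uncertain one by one.

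Values above 0 that did not pass over all 7 arrays in Star CSC were let-7g (0.86), miR-15b (0.72), let-7a (0.52), miR-34a (0.47), miR-21 (0.46) and miR-210 (0.09). Values below 0 were miR-221 (−0.64), miR-193a (−0.79), miR-125b (−0.84) and miR-22 (−1.64), and adjusted p lay from 0.0738 to 0.854. With the slide as a block 31 passed (17 higher, 14 lower), miR-31 among them (adjusted p = 0.0046). The miR-31 call ended in 10 of 23 alternatives (adjusted p up to 0.985), among them without either Star parent array and without Star CSC replicate 1.

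**Figure D1:**
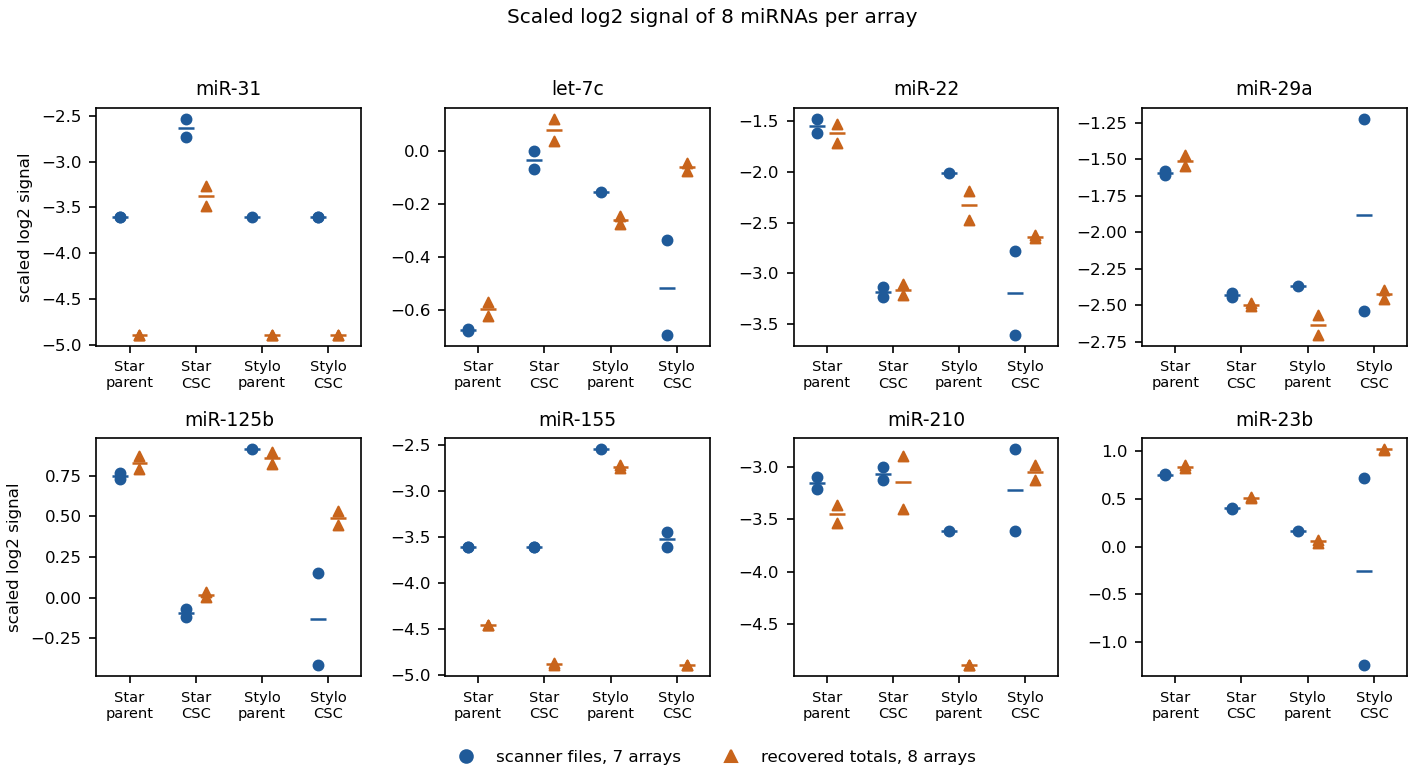
Scaled log2 signal of 8 miRNAs on each array (vertical axis) in the 4 groups (horizontal axis), with blue circles for the 7 scanner arrays, orange triangles for the 8 columns of recovered totals and dashes for group means. In the recovered totals the 2 Stylo parent arrays lie at −2.76 and −2.71 for miR-155, above every other array (highest −4.45), and miR-31 lies above the floor in Star CSC alone.

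Stylo CSC were compared with the Stylo parent as the same contrast in the drug-sensitive line. MiR-155 was again the 1 miRNA of 46 to pass (0 higher, 1 lower; 7 at an unadjusted p below 0.05). It was well above background on 0 of 2 Stylo CSC arrays and at least 1.62-fold lower than in the Stylo parent (log2 change −0.98 ± 0.12, n = 2 and 1; limma, adjusted p = 0.0475). The bound was 2.31-fold in the recovered totals (log2 change −2.15 ± 0.05, adjusted p = 1.27e-05). On slide 1 it was 1.95-fold from 1 array against 1. Every array but that of Stylo parent lay at the floor, so the test there measures no spread of miR-155. Over all 7 arrays this call and that in Star parent share the single Stylo parent array, so they are not independent. That was the only array with miR-155 well above background, and the miRNA was tested only through it.

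In Stylo CSC 9 miRNAs passed in both further sets (2 higher, 7 lower), from 17 of 50 on slide 1 (5 higher, 12 lower) and 17 of 56 in the recovered totals (10 higher, 7 lower). MiR-210 rose by 0.86 and 1.84 from a Stylo parent level not above background, at least 1.36-fold and 2.22-fold, and miR-23b rose by 0.75 and 0.96 but was at −0.42 over all 7 arrays (adjusted p = 0.799). The 7 that fell were miR-155, miR-92a (−1.56, and −2.14 with 1 of 2 Stylo CSC arrays at the floor), miR-15b (−0.78 and −0.55), miR-193a (−0.68 and −0.72), let-7e (−0.61 and −0.47), miR-125b (−0.57 and −0.37) and miR-494 (−0.52 and −0.30, but 0.70 over all 7 arrays, adjusted p = 0.761). In the recovered totals let-7a rose by 0.43, let-7f by 0.45 and miR-34a by 0.52, while on slide 1 let-7a (0.23, adjusted p = 0.0806) and miR-34a (0.23, adjusted p = 0.147) did not pass. The miR-23/27/24 clusters rose as a list in the recovered totals (3 of 3, median 0.71, camera adjusted p = 0.0201, but adjusted p = 0.666 with an estimated correlation), with 1 of 3 on slide 1 (adjusted p = 0.151) and a median of −0.42 over all 7 arrays (adjusted p = 0.729). MiR-138a, a neural marker, was well above background in slide 1's Stylo CSC array and on no other scanner array, at least 1.8-fold above the Stylo parent. Like every slide 1 change in this comparison, this is 1 array against 1, with no measured spread in Stylo. The slide 1 tests take their spread from the Star arrays. MiR-138a was not tested in the other sets.

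Over all 7 arrays miR-342 (1.08, at least 2.11-fold), miR-191 (0.53, at least 1.01-fold) and miR-210 (0.39, no bound), which were not well above background in Stylo parent, did not pass in Stylo CSC. Neither did miR-21 (−0.07), let-7a (−0.31), miR-8824 (−0.56), miR-34a (−0.71), miR-221 (−0.72), miR-8892 (−1.09), miR-193a (−1.14) and miR-22 (−1.19), with adjusted p from 0.252 to 0.964. With the slide as a block 21 passed (3 higher, 18 lower), and miR-155 had adjusted p = 0.000555. The miR-155 call ended in 17 of 23 alternatives (adjusted p up to 0.981), among them a fit of these 2 groups alone and without any 1 of the 4 Star arrays, and the recovered totals gave 11 miRNAs without Stylo parent replicate 2.

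Between the sorted cells of both lines, 3 of 46 miRNAs passed, all higher in Star CSC (3 higher, 0 lower; 7 at an unadjusted p below 0.05). MiR-31 was at least 1.52-fold higher (log2 change 0.97, adjusted p = 0.0171), miR-103, which targets Dicer, 1.74-fold higher (0.80 ± 0.09, adjusted p = 0.0171; well above background on 2 Star CSC and 1 Stylo CSC arrays) and miR-874 at least 1.18-fold higher (0.53 ± 0.08, adjusted p = 0.0422; limma, n = 2 and 2). MiR-31 passed in both further sets too (at least 2.08-fold and 1.48-fold). Its log2 change equals that against Star parent in each set, the distance of Star CSC to the floor. The 2 calls of miR-31 are therefore not independent. MiR-103 and miR-874 passed on slide 1 (0.80, and at least 1.42-fold) and not in the recovered totals (0.64 and 1.44, adjusted p = 0.458 and 0.0773). With normexp on the median signal all 3 turned negative (−0.30, −0.23 and −0.21).

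Further miRNAs higher in Star CSC in both further sets were miR-188 (at least 2.07-fold on slide 1, and 2.06 on the log2 scale in the recovered totals with 1 of 2 Stylo CSC arrays at the floor), let-7e (0.54 and 0.39) and miR-15b (0.43 and 0.42), and lower were miR-23b (−0.33 and −0.51) and miR-494 (−0.14 and −0.30). MiR-23b and miR-494 turned to 0.25 and 0.46 in the recovered totals without scaling, and miR-23b was at 0.66 over all 7 arrays (adjusted p = 0.706). MiR-1249, miR-8843 and miR-8892, all lower in Star CSC, passed on slide 1 but not in the recovered totals, where their sign was opposite. In these totals they lay at the floor on Stylo CSC replicate 1. On replicate 2 each lay above both Star CSC columns, so the opposite sign rests on 1 column at the floor. Slide 1 gave 23 of 50 (14 higher, 9 lower) and the recovered totals 11 of 56 (6 higher, 5 lower), which became 31 (31 higher, 0 lower) without scaling, 20 without Stylo CSC replicate 1 and 7 without Stylo parent replicate 2. The miR-23/27/24 list was lower in the recovered totals (1 of 3 passed, 3 adjusted over the list alone, camera adjusted p = 0.0452, but adjusted p = 0.715 with an estimated correlation), with a median of −0.44 that turned to 0.32 without scaling and was 0.53 over all 7 arrays. Values not past the threshold over all 7 arrays were miR-34a (1.27), let-7a (0.41), let-7f (0.21), miR-210 (0.15) and miR-221 (0.07). Below 0 were miR-21 (−0.14), miR-197 (−0.83) and miR-342 (−0.88), with adjusted p from 0.256 to 0.881. With the slide as a block 26 passed (15 higher, 11 lower). The calls of miR-31, miR-103 and miR-874 ended in 11, 15 and 15 of 23 alternatives, among them without either Star parent array and without Star CSC replicate 1, and each of miR-103 and miR-874 without Star CSC replicate 2.

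The change on sorting was then compared between the lines, as Star CSC minus Star parent against Stylo CSC minus Stylo parent. Over all 7 arrays 0 of 46 miRNAs passed (limma; 8 at an unadjusted p below 0.05), while 20 of 50 passed on slide 1 (10 higher, 10 lower) and 19 of 56 in the recovered totals (10 higher, 9 lower), 14 of them in both. MiR-92a differed by 2.65 and 3.72 (log2, positive where the change was more positive in Star), miR-155 by 0.96 and 1.73, miR-31 by 1.05 and 1.51, and miR-15b, which rose in Star CSC and fell in Stylo CSC, by 1.44 and 1.48. Let-7e (1.03 and 0.99), let-7b (0.68 and 0.52) and let-7c (0.57 and 0.48) also differed upward. MiR-191 (−1.25 and −2.04), miR-210 (−0.85 and −1.54), miR-23b (−1.17 and −1.29), miR-27b (−0.89 and −1.26), miR-22 (−1.12 and −1.23), miR-29a (−0.93 and −1.20) and miR-23a (−0.53 and −0.79) differed downward, but miR-23b and miR-27b were at 0.07 and 0.29 over all 7 arrays. Those of miR-155, miR-191, miR-210 and miR-92a are partly set by the floor, and that of miR-31 wholly. Each was undetected or not well above background in at least 1 group or array. The value of miR-31 is the distance of Star CSC to the floor, as in both comparisons of Star CSC above. In the recovered totals all 14 except miR-31 had the opposite sign in Star against Stylo parent (miR-92a −2.04, miR-23b 0.78). The contrast contains that parent difference, so these values alone do not tell a different response to sorting from a different starting level of the parents.

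As lists, the let-7 family differed upward in all 3 sets. Over all 7 arrays its median was 1.03 and 0 of 6 members passed by limma (3 at an unadjusted p below 0.05, 2 adjusted over the list alone; camera adjusted p = 0.0342, but 0.144 with scaling over all probes, 0.236 with quantile normalization and 0.525 without scaling). On slide 1, 4 of 6 passed (adjusted p = 0.0163), and in the recovered totals 3 of 6 (adjusted p = 0.0389). With an estimated correlation these became adjusted p = 0.434, 0.791 and 0.297. The miR-23/27/24 clusters differed downward, 3 of 3 in both further sets (adjusted p = 0.0696 on slide 1 and 0.0133 in the recovered totals, and adjusted p = 0.791 and 0.297 with an estimated correlation), with a median of 0.07 over all 7 arrays. The values of miR-15b (1.38), let-7g (1.06), let-7a (0.83), miR-21 (0.52), let-7f (0.49) and miR-221 (0.08) did not pass over all 7 arrays. Nor did those of miR-210 (−0.30), miR-23a (−0.34), miR-191 (−0.90), let-7c (a ratio of 2.01) and miR-34a (a ratio of 2.26). Of these let-7g, miR-191 and miR-210 were not well above background in Stylo parent. With the slide as a block 30 passed (21 higher, 9 lower). Across miRNAs, which are not independent replicates, the changes on sorting in Star and in Stylo correlated at r = 0.139 and rho = 0.0852 over all 7 arrays (46 miRNAs, 19 with the same sign), r = −0.0229 on slide 1 (50 miRNAs) and r = 0.0347 in the recovered totals (56 miRNAs). The 2 changes share no array.

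**Figure D2:**
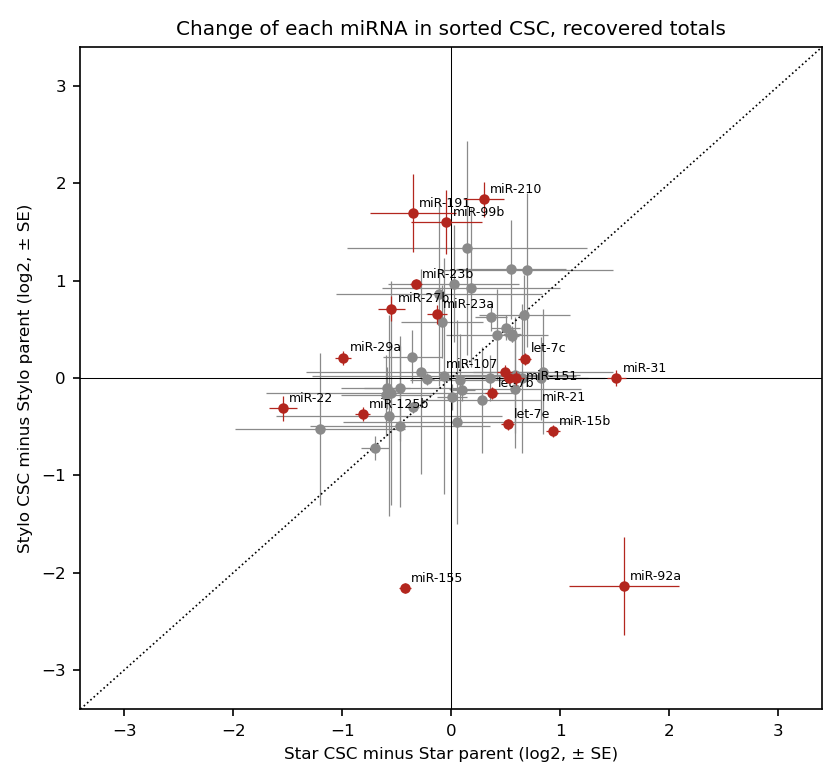
Log2 change of each of 56 miRNAs on sorting in Star (Star CSC minus Star parent, horizontal axis) and in Stylo (Stylo CSC minus Stylo parent, vertical axis) in the recovered totals, with bars for ± SE and a dotted line where both changes are equal. The 19 miRNAs whose changes differed past an adjusted p of 0.05 are red and named, with miR-92a and miR-31 to the right of the line and miR-210 and miR-191 above it.

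Of the lists fixed beforehand, those named after function did not pass camera in any of the 5 comparisons and 3 sets. Over all 7 arrays, 1 of 8 tested oncogenic miRNAs fell in Star parent against Stylo parent (miR-155; camera adjusted p = 0.729), and on slide 1, 3 rose and 1 fell (adjusted p = 0.447). Of 4 tested miRNAs named in drug efflux or doxorubicin resistance, 0 passed in that comparison over all 7 arrays by limma (0 at an unadjusted p below 0.05; camera adjusted p = 0.704). In this list miR-27b, which represses CYP1B1, rose in both further sets. Of 5 tested miRNAs named in breast cancer stem cells, 0 passed by limma in Star CSC against the parent over all 7 arrays (1 at an unadjusted p below 0.05; camera adjusted p = 0.596), and 4 rose on slide 1 (let-7a, let-7b, let-7c and miR-34a; camera adjusted p = 0.184). Of 3 tested tumour-suppressor miRNAs, miR-31 rose in Star CSC over all 7 arrays (camera adjusted p = 0.798 for the list), and on slide 1 miR-31 and miR-34a rose while miR-125b fell. The 3 to 5 tested members of the miR-17-92 clusters did not pass as a list (adjusted p = 0.993 for Star against Stylo parent over all 7 arrays).

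Among markers of other sources, 2 of 8 haematopoietic miRNAs were well above background on any scanner array, miR-155 and miR-223, a myeloid miRNA. On slide 1, miR-223 was at least 1.53-fold lower in Star parent and at least 1.96-fold lower in Stylo CSC than in Stylo parent (log2 changes −0.62 and −0.97, adjusted p = 0.022 and 0.0129), moving in the direction of miR-155. The 3 tested serum-abundant miRNAs (miR-16, miR-92a and miR-223) all fell in both of these comparisons on slide 1, with list medians of −0.62 and −0.97. The list did not pass camera in either. Cells of all 4 groups were grown in 10% fetal bovine serum, and serum as a source of these miRNAs was not tested. In the recovered totals 1 of 3 passed in each, miR-92a, which was lower. For Stylo CSC the list median was −0.39. For Star parent it was 0.32 although camera's direction was down (adjusted p = 0.643). MiR-16 and miR-223 lay at the floor on Stylo CSC replicate 1 and Stylo parent replicate 2, so their signs there measure little. Of the remaining families, let-7 had 6 of 9 members well above background on any array, the miR-183 cluster 1 of 3 and the miR-34 family 1 of 5. The miR-15 family had 2 of 7, miR-29 had 1 of 3, miR-30 had 1 of 5, miR-221 and its neighbour miR-222 had 2 of 2, and miR-103 with miR-107 had 2 of 2. The miR-125 group had 2 of 6 (miR-125b and miR-99b), the miR-500 cluster 1 of 6 (miR-188) and the imprinted DLK1-DIO3 cluster 1 of 37 (miR-494). The miR-181, miR-26, miR-130, miR-148 and miR-302 groups had 0 members well above background.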

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

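The tests weighed in this part were chosen after the results were seen, except the fit without scaling over all 7 arrays and the limma interaction contrast, which were fixed before. The array of Stylo CSC replicate 1 differed from all others, and 3 explanations were tested. A dim array is argued against, since over the 17 miRNAs bright on every array its highest correlation with another array was 0.614, below the lowest of the other pairs (0.931). The sorted state of Stylo is argued against too, since Stylo CSC replicate 2 correlated with the other groups' arrays at 0.954 or more. A hybridisation difference between the 2 slides may account for it, since 5 of 6 control probe types on this array lay outside the range of the other 6 arrays. The design puts no other array on slide 2, so a slide effect, a mishandled array and another RNA sample stay open.

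MiR-155 was higher in Stylo parent than in the other groups. A single Stylo parent array as the cause is argued against by the value table alone. Its second Stylo parent column lay 1.74 (log2) above the highest array of the other groups. That column differs from its scanner file, which holds the values of replicate 1. Whether it stems from a separate Stylo parent sample is therefore not known. RNA from blood cells stays open. The myeloid miR-223 was at least 1.5 (log2) lower on the second Stylo parent column than on the first while miR-155 differed by −0.0405 (first minus second). Yet 5 of 10 other miRNAs within 0.5 (log2) of miR-223 on the first column were undetected on the second too, and on slide 1 miR-223 fell with miR-155. Against it, the change of miR-223 between Star and Stylo parent was 0.62 in the recovered totals (adjusted p = 0.767), with 1 of 2 Stylo parent columns at the floor. Also, of 7 other haematopoietic miRNAs 1 was detected on the first column (miR-223) and 0 on both, and miR-142, miR-144, miR-150 and miR-451 were above background on 0 arrays, though values at the floor exclude little. Scaling between arrays as the whole cause is argued against, since without it the change between Star and Stylo parent went from −1.72 ± 0.05 to −1.39 ± 0.16 in the recovered totals, where Star parent was detected (adjusted p = 0.00414). Over all 7 arrays it went from −1.06 ± 0.12 to −0.53 ± 0.11 and the call ended (adjusted p = 0.176), as did that of Stylo CSC against parent (−0.98 to −0.53, adjusted p = 0.399). There 6 arrays lay at the floor without scaling, so −0.53 is the distance of Stylo parent to it and decides nothing. A loss of miR-155 both in the resistant line and in the sorted Stylo cells was not tested apart from blood RNA, and differences in culture between the groups were not tested.

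The value table's columns of Stylo CSC replicate 1 and Stylo parent replicate 2, whose values differ from their scanner files, held 30 and 25 miRNAs above the undetected value, against 48 to 72 in the other 6 columns. Their undetected value was 6.15 against −0.941 to 0.293 in the others. The 2 Stylo parent columns correlated at r = 0.989 over 22 miRNAs detected in every column and at 0.909 over all 56 tested, where Star parent replicate 1 and Stylo parent replicate 1 correlated at 0.92.

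In the recovered totals 14 miRNAs that also passed on slide 1 changed differently on sorting in the 2 lines, by the limma interaction test. MiR-92a (3.72), miR-155 (1.73), miR-31 (1.51), miR-15b (1.48), let-7e (0.991), let-7b (0.525) and let-7c (0.475) changed more positively in Star. MiR-23a (−0.786), miR-29a (−1.20), miR-22 (−1.23), miR-27b (−1.26), miR-23b (−1.29), miR-210 (−1.54) and miR-191 (−2.04) changed more positively in Stylo. MiR-31 lay at the floor in every group but Star CSC, so its value is the distance of Star CSC to the floor. In these totals all 14 except miR-31 had the opposite sign in Star against Stylo parent (miR-92a −2.04, miR-23b 0.78). The interaction test contains that parent difference, so these values alone do not tell a different response to sorting from a different starting level of the parents. Over all 7 scanner arrays none passed (0 of 46 by limma, 8 at an unadjusted p below 0.05).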

How the results depend on the processing

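Normexp on the median signal and the recovered totals with their own alternatives were chosen after the data were examined; the other alternatives were fixed before. Counts below follow the order Star against Stylo parent, Stylo CSC against parent, Star CSC against parent, Star CSC against Stylo CSC, difference of the CSC changes, and lists past the threshold, which over all 7 arrays were 1, 1, 1, 3, 0 and 2. Counts within 1.5 times of these are left out. Square brackets give the limma count at an unadjusted p below 0.05 where 0 passed. The cause was not tested unless stated.

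With scaling over all probes the first 4 counts were 0 [2], 0 [1], 0 [2] and 0 [1], with 0 lists. Quantile normalization gave 0 [6], 0 [4], 3 (3 higher), 5 (5 higher), 1 and 0 lists, and no scaling 0 [6], 0 [2], 11 (11 higher, 0 lower), 15 (15 higher, 0 lower), 3 and 0 lists. The median log2 change over all tested miRNAs in the 5 comparisons was −0.246, −0.253, 0, 0.055 and 0.384, without scaling 0.174, −0.00767, 0.533, 0.792 and 0.598, and with scaling over all probes −0.713, −0.745, 0.758, 0.753 and 1.49, so every direction is relative to the scaling. The deposited total gene signal gave 0 [7], 0 [5], 0 [4], 0 [7] and 0 lists, and the deposited value table as it stands 0 [2], 0 [1], 0 [0], 0 [0] and 0 lists. The brightest probe gave 0 [9], 0 [9] and 1 list, and the mean of log2 probe values 0 [9], 0 [10] and 2 for Star CSC against parent. No filter on dim miRNAs gave 6 (0 higher, 6 lower), 6 (0 higher, 6 lower), 0 [10], 0 [9], 6 (6 higher, 0 lower) and 7 lists. Only miRNAs above background on all arrays gave 0 [1], 0 [1], 0 [3], 0 [1] and 5 lists, with a correlation of the CSC changes of −0.255 in place of 0.139. A lower floor gave 0 [5], 0 [5], 1 for Star CSC against Stylo CSC and 1 list, and eBayes with trend 2 for the difference of changes. Only the 2 groups compared gave 28 (9 higher, 19 lower), 0 [0], 31 (17 higher, 14 lower) and 0 [4]. An unadjusted p with a 2-fold change gave 2, 4, 0 [7] for Star CSC against Stylo CSC and 3 for the difference. Entering the identical arrays separately gave 5, 3, 9 and, for the difference, 8. Normexp on the median signal gave 0 [15], 0 [7], 4 (0 higher, 4 lower), 1 (0 higher, 1 lower) and 8 lists, with a correlation of −0.188. The planned normexp on mean signals was not run, since the files hold no such column.

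The slide as a block gave 32, 21, 31, 26, 30 and 5 lists. By construction it leaves the array of Stylo CSC replicate 1 without weight. The recovered totals gave 18, 17, 20, 11, 19 and 7 lists, against which the scanner files gave 1, 1, 1, 3, 0 and 2 lists, and without Stylo CSC replicate 1 gave 20, 17, 26, 23, 20 and 2 lists. Only miRNAs detected on all arrays gave, in the recovered totals, 12 (5 higher, 7 lower) for the difference of changes. Without scaling these totals gave 17 (14 higher, 3 lower), 13 (9 higher, 4 lower), 20 (18 higher, 2 lower), 31 (31 higher, 0 lower) and 17 (12 higher, 5 lower), against 10 and 8, 10 and 7, 11 and 9, 6 and 5, and 10 and 9 with it.

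Leaving out 1 array at a time gave 0 to 32, 0 to 32, 0 to 31, 0 to 36, 0 to 33 and 0 to 6 lists from the scanner files, with a correlation of −0.0229 to 0.197. From the recovered totals it gave 6 to 20, 11 to 22, 14 to 22, 7 to 20, 15 to 26 and 2 to 9 lists, with a correlation of −0.0614 to 0.133. Each 0 among the first 4 came from leaving out a Star array, and the highest counts of the scanner files from leaving out Stylo CSC replicate 2, which takes the spread between the 2 Stylo CSC arrays out of the fit. A lone array is assumed to vary like the other groups. The replicate number as a replicate block gave 0 [5], 0 [5], 0 [10] and 0 [6] for the first 4 comparisons, and moved no count of the recovered totals by over 1.5 times. With this block 8 of 39 named results of the recovered totals lost their call. Same-numbered samples did not deviate together in every pair of groups (correlations −0.364, −0.052 and −0.03 from the scanner files, and −0.577, −0.5, −0.154, −0.104, 0.148 and 0.475 from the recovered totals), so the numbers were not taken to pair the samples.

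Of 1914 values of 95 named results under 31 settings, 1563 kept their side of the threshold, 169 lost the call, 162 gained it and 20 reversed. A change of sign was counted as reversed only where the value passed under at least 1 of the 2 settings. MiR-21 turned to 0.76 in Star CSC against Stylo CSC without scaling, and to 0.264 in Stylo CSC against parent without Stylo CSC replicate 2. Against Stylo CSC, miR-103 turned to −2.46 with the deposited value table and to −0.23 with normexp, miR-31 to −0.296 and miR-874 to −0.21 with normexp, and miR-31 to −0.0894 against Star parent. With the recovered totals let-7a turned to 0.433 and miR-34a to 0.518 in Stylo CSC against parent. Without scaling of the recovered totals miR-23b turned to 0.198, miR-331 to 0.30 and miR-494 to 0.168 in Star CSC against parent, miR-23b to 0.249 and miR-494 to 0.456 against Stylo CSC, and miR-494 to 0.087 in Star against Stylo parent. Where the recovered totals are set against the scanner files, the latter gave 0.0689 for miR-23b and 0.294 for miR-27b in the difference of changes, 0.66 for miR-23b in Star CSC against Stylo CSC, and −0.423 for miR-23b and 0.704 for miR-494 in Stylo CSC against parent. Few spots stood well above background (4.19% to 8.78%), and 46 of 454 miRNAs were tested over all 7 arrays.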

Other observations

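The test in this part was written before its result was seen, and was run on recovered totals chosen after the data were examined. Some miRNAs passed in 1 of the further sets alone. In the recovered totals miR-99b, which lies in a cluster with let-7e and miR-125a in mammals, was at least 1.5-fold higher in Star parent and at least 1.88-fold higher in Stylo CSC than in Stylo parent (limma, log2 changes 1.28 ± 0.32 and 1.60 ± 0.32, adjusted p = 0.0386 and 0.0202). MiR-107, which shares its seed with miR-103, rose by 0.53 ± 0.05 in Star CSC against the parent and was at least 1.04-fold higher there than in Stylo CSC, where it was undetected (adjusted p = 0.00157 and 0.000389). MiR-151 was at least 1.51-fold higher in Star CSC than in Star parent (0.59 ± 0.07, adjusted p = 0.00269). MiR-155 fell by 0.42 ± 0.05 in Star CSC against the parent, to a level detected on 1 of 2 arrays (adjusted p = 0.00269).

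On slide 1 miR-16, the partner of miR-15b in a cluster, rose by 0.41 ± 0.02 in Star CSC against the parent (limma, adjusted p = 0.00759) and was at least 1.34-fold lower in Stylo CSC than in its parent (adjusted p = 0.0125). MiR-188 was at least 1.65-fold and miR-92a at least 1.91-fold higher in Star CSC than in Star parent (adjusted p = 0.00568 and 0.00809), and let-7g rose by 0.79 ± 0.05 (adjusted p = 0.00759). MiR-197 fell by 0.46 in Star CSC and was lower than in Stylo CSC by 1.19 on the log2 scale (log2 change −1.19 ± 0.12, adjusted p = 0.0176).

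The changes of Stylo CSC and of Star parent, both against Stylo parent, resembled each other in the recovered totals (r = 0.76, covariance 0.432 over 56 miRNAs). Unchanged groups simulated with shared controls gave r = 0.516 and covariance 0.163 (medians of 1000 simulations). The noise was drawn from a spread pooled over the 4 groups and not from the Stylo parent columns, so these medians may understate the effect of shared controls. A profile of the Stylo parent cells present on both of their arrays was set out as a possible explanation, to be kept only if the covariance stayed above 0.1 with the 2 Stylo parent arrays split between the changes. The smaller split covariance was 0.0866 (r = 0.0957) and the other 0.338 (r = 0.515). The 2 splits lie on either side of the bound, so that explanation cannot be told apart from the shared controls with 2 Stylo parent arrays.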
